A study of Schizosaccharomyces pombe with 28 samples.

How the data were processed

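Transcript abundance was measured in the fission yeast Schizosaccharomyces pombe on 28 Affymetrix yeast arrays, which carry probe sets for fission yeast and for budding yeast. Strains were grown to mid-log phase in rich medium, polyA RNA was purified from total RNA, and the RNA was amplified and labelled with biotin. The arrays came from 3 projects numbered 488, 529 and 582 by the submitters. Project 488 held 3 wild type (WT) and 3 zfs1-null samples, project 529 held 5 of each, and project 582 held 3 samples each of WT, zfs1-null, cbf12-null and the double null of both genes. The series text calls the samples biological replicates. Whether each came from its own culture is not given in the sources used here, so the p-values measure only the spread between these samples.

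The authors deposited 1 intensity per probe set and array, a MAS5 signal on a linear scale, for 10928 probe sets. MAS5 condenses the probes of a probe set into 1 signal on each array separately and then scales each array. Its version, its scaling settings and its detection calls are not given in the sources used here. In the deposited values the mean after trimming 2 percent at each end lay between 500.1 and 500.2 on all 28 arrays. Scaling of this kind sets the arrays' means equal, so a change shared by most transcripts would not be visible, and the split between higher and lower genes depends on it. Amplification before labelling can compress or distort differences, and its effect on single transcripts was not measured here.

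Of the 5538 probe sets listed in the array's gene table, 2917 named 1 S. pombe gene, 20 named several genes and were left out, and 2601 named another species. A further 5390 probe sets were not listed, 213 of them controls. S. pombe symbols were taken from an annotation of assembly ASM294v3, which updated 113 symbols, and 3 probe sets (yox1, otu1 and wtf1) were matched by exact symbol only. The gene named pfl8 here is SPAC1F8.06, which the array's table calls fta5. As the array's build is not given in the sources used here, no coordinates are printed. For genes with several probe sets the one with the highest mean log2 signal was used, which left 2899 genes.

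Background was taken on each array as the percentile 95 of the other-species probe sets, between 3.65 and 5.44 signal units. Between 2896 and 2899 of the S. pombe genes lay above it on each array. The number of arrays limits the precision. The median over genes of the SD between replicates was 0.07 to 0.14 on the log2 scale, highest in the double null. Pearson correlations across genes within a group averaged 0.976 to 0.995 per array, and genes are not independent replicates.

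Linear models were fitted to log2 signals with limma 3.58.1 in R 4.3.3, with moderated statistics and an intensity trend in the prior variance. All tests were two-sided. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 over the 2899 genes of a comparison. The combined comparison of zfs1-null with WT used 22 arrays with a term for project, and the same comparison was fitted within each project. A further model tested whether the zfs1 effect differed between projects. In project 582 the 4 strains were fitted together, giving the effect of cbf12 deletion with and without Zfs1, the effect of zfs1 deletion with and without Cbf12, the double null against WT, and the interaction of both deletions. For the deleted genes, fold changes were computed against the background level where the signal lay below it, and are lower bounds.

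The 22 gene lists, the rule for named genes, the comparisons and most alternatives were chosen before the data were examined. Lists were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other genes, and adjusted over the 22 lists of each of 4 comparisons. Each was repeated with an estimated correlation and with fry, which tests whether a list's own genes move on balance one way. The rule named zfs1 and cbf12. It named the 14 largest rises and 8 largest falls of the combined zfs1 comparison that had the same sign in all 3 projects, and the 8 largest of each direction for both cbf12 comparisons and the interaction. It named 3 of each direction for the double null and for zfs1 deletion without Cbf12, and 4 genes for the difference between projects. It also named all measured flocculins and flocculation regulators, up to 4 called members of each other list, and up to 2 of the brightest where none was called.

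The script was tested on simulated data of the same design, with 200 changed genes among 2899. In the combined comparison it recovered 100 percent of 2-fold and 99.0 percent of 1.5-fold changes. For cbf12 deletion in the WT background it recovered 98.0 and 90.0 percent, and for the interaction 89.0 and 65.0 percent. Of the genes it called, 2.45, 4.57 and 6.67 percent were unchanged ones. The simulated noise was independent between genes, so these shares do not cover variation that many genes of an array share.

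Alternatives changed the normalization between arrays, the pseudocount, the probe sets used, the variance model, weights for arrays, the fold minimum, replicate number as a block, the term for project, the arrays in the fit, and each replicate in turn. A search for AU-rich elements in 3′ untranslated regions was planned and was not run, because no genome sequence was used here. Array scans and detection calls were not used here.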

Results

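The arrays measured polyA RNA from 4 strains of S. pombe. Zfs1 is a zinc finger protein of the tristetraprolin family, which binds AU-rich elements in mRNAs and promotes their decay, and Cbf12 is a DNA-binding transcription factor of the CSL family that promotes cell adhesion and flocculation. The series title places the work on transcripts for proteins of cell-cell interaction and their control by Zfs1. The deleted genes were lost from the arrays. The zfs1 signal was at least 114-fold lower in the zfs1-null strain of project 488, at least 81.3-fold lower in project 529 and at least 87.7-fold lower in project 582. The cbf12 signal fell from 184 ± 12.7 (SD, n = 3) in WT to 0.40 ± 0.23 (n = 3) in the cbf12-null strain, at least 38.1-fold lower.

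The first comparison asked which transcripts change when Zfs1 is absent. Those that rose most were arz1 (SPCC1494.03), named as a Zfs1 target, pfl8 (SPAC1F8.06), a flocculin-like cell surface glycoprotein, and cbf12 (SPCC1223.13) itself. Over the 3 projects arz1 rose 3.45-fold (log2 1.79 ± 0.05 SE, adjusted p = 6.4e-21), pfl8 rose 3.45-fold (1.79 ± 0.09, adjusted p = 1.7e-14) and cbf12 rose 2.36-fold (1.24 ± 0.07, adjusted p = 3.3e-13). In project 529 the arz1 signal was 430 ± 21.5 (SD, n = 5) in WT and 1416 ± 17.7 in the zfs1-null strain. The log2 change of arz1 was 1.85, 1.72 and 1.83 in projects 488, 529 and 582, that of pfl8 1.87, 1.98 and 1.38, and that of cbf12 1.27, 1.16 and 1.33. In project 582 the cbf12 rise passed when only WT and the zfs1-null strain were fitted (SE 0.12, adjusted p = 6.0e-05). It did not pass in the fit of all 4 strains (SE 0.44, adjusted p = 0.0626), where the spread includes arrays that lack the gene and lie below background.

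Other named rises were smaller. The log2 rises were 0.92 for rev3, the catalytic subunit of DNA polymerase zeta, 0.91 for mus7, a replication repair protein, and 0.77 for mus81, a structure-specific endonuclease. The oxidation resistance gene oxr1 rose by 0.98, the transcription factor grt1 by 0.85, the Mediator kinase srb10 by 0.84, the cyclin psl1 by 0.82, the ubiquitin-conjugating enzyme ubc6 by 0.79, fhn1 by 0.72, the G protein subunit git11 by 0.70 and nep1 by 0.70. Among the largest falls, the log2 change was -1.89 ± 0.10 SE (adjusted p = 2.1e-14) for mei2, an RNA-binding protein needed for meiosis, -1.77 for mfm1, a precursor of the M-factor pheromone, and -1.39 for the meiotic cyclin rem1. A second, dimmer probe set of mfm1 gave -2.75. Also lower were dak2, a dihydroxyacetone kinase (-1.77), str3, a transporter of iron compounds (-1.57), mug153 (-1.49) and the amino acid permease isp5 (-1.41).

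In all, 1207 of 2899 genes changed on zfs1 deletion over the 3 projects, 677 higher and 530 lower. Of these, 3 rose and 17 fell at least 2-fold. The change had the same sign in all 3 projects for 1050 genes (87.0 percent), which is expected in part because the same arrays were used to call them, and 148 were called in each project alone. Without a term for project the count was 481, 28 of 92 called gene values examined lost their calls, among them grt1 and gst2, and with all probe sets of both species tested the count was 1881. The call of str3 was lost under quantile normalization. Setting array medians equal gave 537 higher and 625 lower, against 677 and 530, and quantile normalization gave 659 and 601.

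**Figure D1:**
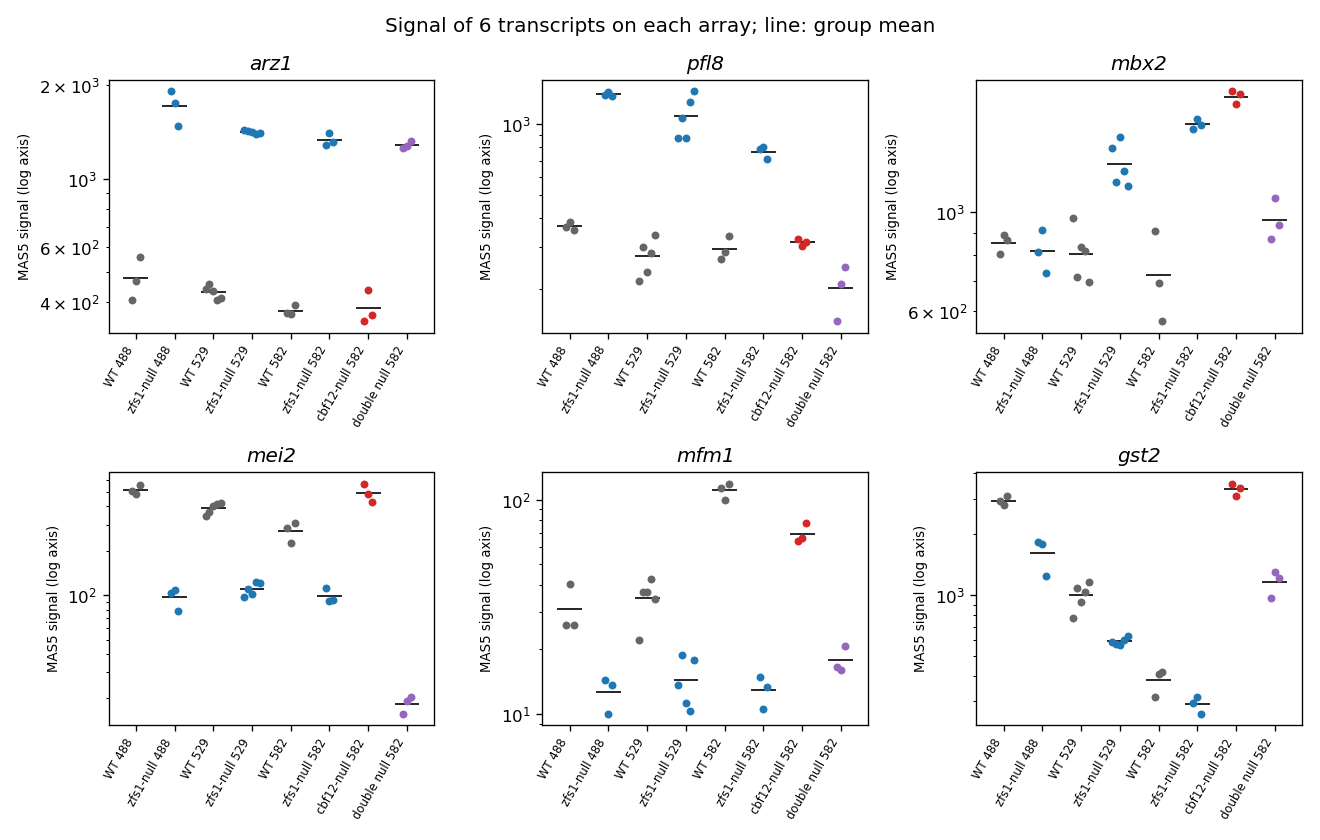
MAS5 signal on a log axis for arz1, pfl8, mbx2, mei2, mfm1 and gst2. Each point is 1 array, the line is the group mean, and groups are strains within projects 488, 529 and 582. The signal of arz1 was higher in every zfs1-null group, including the double null (1283), while pfl8 in the double null (201) lay below its WT level in project 582 (295).

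Flocculins and their regulators were tested as lists. Of the 3 measured flocculins and adhesins, pfl8 and map4 (0.24, adjusted p = 0.032) rose and 1 did not pass (camera adjusted p = 0.0332, and adjusted p = 0.264 with an estimated correlation). The other 10 of 13 listed were not on the arrays' gene table. Leaving out single arrays, for example replicate 2 of WT in project 529, ended the call of map4. Of 12 flocculation regulators 6 rose (camera adjusted p = 0.0151, and 0.177 as the adjusted p with an estimated correlation). They were cbf12, the MADS box activator mbx2 (0.60), the LIM domain-binding gene ldb1 (0.50), the MBF cofactor yox1 (0.46), adn3 (0.20) and the corepressor tup11 (0.19). The other 6 did not pass, among them the kinase lkh1 (0.08), ssn6 (0.07) and cbf11 (-0.08). The call of adn3 was lost without replicate 1 of WT in project 582 and under per-array median scaling.

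Cell cycle and translation genes were more often higher. Of 10 G1/S genes 4 rose, among them the cyclin cig2 (0.55) and the replication licensing factor cdc18 (0.43) (camera adjusted p = 0.0257, adjusted p = 0.344 with an estimated correlation). Of 12 mitosis genes 7 rose, among them slp1, an activator of the anaphase-promoting complex (0.55), and the ring protein cdc15 (0.33) (0.0151, adjusted p = 0.344 with an estimated correlation). Of 10 histone genes 7 rose, with hht3 at 0.36 and htb1 at 0.24 (0.0151, adjusted p = 0.264 with an estimated correlation). Of 112 ribosomal protein genes 35 rose and none fell, with a median of 0.08 (0.000155, adjusted p = 0.595 with an estimated correlation).

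Genes of mating, meiosis, stress, iron uptake and subtelomeres were more often lower. Of 26 mating and pheromone response genes 15 fell and 3 rose, with ste4, an adaptor of the pheromone MAP kinase pathway, at -0.67 (camera adjusted p = 0.000179, adjusted p = 0.236 with an estimated correlation). Of 7 M cell genes 3 fell, the M-factor genes mfm1, mfm2 (-0.64) and mfm3 (-0.61) (0.0257, adjusted p = 0.264 with an estimated correlation). Of 24 meiosis and sporulation genes 11 fell and 3 rose, with the spore wall gene isp3 at -1.14 and the recombination gene rec12 at -0.58 (0.00377, adjusted p = 0.264 with an estimated correlation). Of 18 core stress genes 10 fell and 1 rose, with the catalase ctt1 at -0.54 and tms1 at -0.44 (0.00304, adjusted p = 0.262 with an estimated correlation). Of 13 iron uptake genes 6 fell and 1 rose, with the iron permease fip1 at -0.60 and the siderophore synthetase sib1 at -0.46 (0.0254, adjusted p = 0.157 with an estimated correlation). Of 10 subtelomeric genes 6 fell and 1 rose, with dak2 and the galactose enzyme gal10 (-1.14) lowest and say1 at 0.47 (0.000797, adjusted p = 0.0167 with an estimated correlation). Under quantile normalization the calls of histones (adjusted p = 0.0526), M cell genes (0.137), meiosis (0.188) and iron uptake (0.181) were lost.

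The remaining lists did not pass the test on zfs1 deletion. The counts of genes higher and lower were 6 and 6 of 25 for cell wall synthesis, 2 and 0 of 6 for cell separation, 2 and 1 of 4 for P cell genes, 3 and 3 of 16 for iron-using proteins, 1 and 1 of 3 for phosphate and zinc starvation, and 2 and 4 of 8 for hexose transporters. They were 3 and 2 of 14 for glycolysis and fermentation, 1 and 4 of 15 for auxotrophic markers, 6 and 0 of 19 for mRNA decay and 5 and 3 of 15 for zinc finger and RNA-binding proteins, a list that holds zfs1. Their camera adjusted p ranged from 0.108 to 0.932. The median, the mean and the test differed in sign for phosphate and zinc starvation (-0.04, 0.03 and down), glycolysis (0.06, -0.04 and up) and zinc finger proteins (0.03, -0.49 and up). Adjusted over the list alone, the counts differed from those over all genes for flocculation regulators (6 higher and 1 lower), mitosis (7 and 1), meiosis (4 and 12), core stress (2 and 10) and ribosomal proteins (28 and 0).

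Some genes answered the loss of Zfs1 differently in the 3 projects. The alpha-galactosidase gene mel1 had log2 changes of -1.50, 0.38 and -0.15 in projects 488, 529 and 582, and the enolase eno102 had -0.76, 0.20 and 0.58. The meiotic gene meu10 had -0.01, -0.34 and -1.44, and alr2 had 0.65, -0.33 and -1.14. Their adjusted p for the difference between projects ranged from 2.2e-07 for mel1 to 5.5e-07 for alr2. The regulator mbx2 had -0.07, 0.67 and 1.15 (adjusted p = 0.000228), while arz1 did not pass this test (0.596). In all 571 of 2899 genes passed it.

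Within projects the count was 570 genes in project 488 (286 higher, 284 lower), 1223 in project 529 (746 higher, 477 lower) and 327 in project 582 (120 higher, 207 lower). Across genes, the Pearson r of log2 changes was 0.64 between projects 488 and 529, 0.66 between 488 and 582 and 0.63 between 529 and 582. By rank the correlations with project 529 were lower, with Spearman values of 0.44, 0.62 and 0.43 in the same order. Genes are not independent replicates. Without WT replicate 1, WT replicate 2 or zfs1-null replicate 1 the count of project 488 was 323, 312 and 375. In project 582 it was 183 and 194 without zfs1-null replicate 2 or 3, and 544 without double null replicate 2. After setting the array medians equal, the split of project 529 was 491 higher and 739 lower, and under quantile normalization 47.8 percent of the genes called in project 582 were higher, against 36.7 percent.

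The next comparison asked what loss of Cbf12 does when Zfs1 is present. The largest rise was that of gst2. The glutathione transferase gst2 (SPCC965.07c) rose 8.78-fold (log2 3.13 ± 0.13 SE, adjusted p = 8.9e-11), from 383 ± 58.5 (SD, n = 3) to 3334 ± 238. The hexose transporter family member ght3 rose 7.21-fold (2.85 ± 0.16, adjusted p = 3.4e-09), mel1 5.43-fold, the GABA transaminase uga1 4.94-fold, eno102 4.58-fold and the sulfiredoxin srx1 4.19-fold. The log2 rise was 1.84 for mug14 and 1.82 for wtf3, of the wtf spore killer family. Lower were grt1 (-1.98 ± 0.22, adjusted p = 8.1e-06), the cortical dynein anchor num1 (-1.62), the kinase ppk33 (-1.58), the meiotic linear element gene rec10 (-1.53), isp5 (-1.49), tti2 (-1.48) and the ferric reductase frp1 (-1.39). When the WT level was estimated without the WT arrays of project 582, num1 was at -0.58, ppk33 lost its call (-0.21) and eno102 was at 1.46. That level rests on the zfs1-null arrays of project 582 and the zfs1 effect of the other projects. A zfs1 effect that differs between projects therefore moves it too. WT of project 488 minus WT of project 529 gave log2 differences of 2.29 for uga1, 1.70 for mel1, 1.56 for gst2 and 0.83 for srx1. For the other named rises this difference was -1.10 for mug14, -0.49 for ght3, -0.21 for eno102 and -0.16 for wtf3.

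Of 18 core stress genes 14 rose and 1 fell on cbf12 deletion, including tms1 (1.53) and the metallothionein zym1 (1.44) (camera adjusted p = 8.5e-14, adjusted p = 0.00422 with an estimated correlation). Of 8 hexose transporters 3 rose (0.00994, adjusted p = 0.0955 with an estimated correlation), and of 14 glycolysis genes 4 rose (0.000132, adjusted p = 0.0955 with an estimated correlation). All 6 cell separation genes fell, among them the glucanase eng1 (-0.69) and adg2 (-0.78) (0.00948, adjusted p = 0.0955 with an estimated correlation). Of 10 subtelomeric genes 2 rose, eno102 and dak2 (1.07), and 1 fell (0.020, adjusted p = 0.0955 with an estimated correlation). Of 16 iron-using genes 3 rose (0.0334, adjusted p = 0.337 with an estimated correlation), and of 112 ribosomal protein genes 1 rose (1.2e-05, adjusted p = 0.694 with an estimated correlation). The direction of the ribosomal list turned under quantile normalization (adjusted p = 0.212), where hexose transporters (0.0848), glycolysis (0.0710) and iron-using genes (0.384) were also lost. With the WT level estimated without the WT arrays of project 582, the subtelomeric (adjusted p = 0.0910, with dak2 at 0.27), iron-using (0.976), glycolysis (0.468) and ribosomal (0.658) lists were lost, zym1 was at 0.89, and core stress, hexose transporters, cell separation and, newly, M cell genes (3 of 7 higher, adjusted p = 0.00435) passed.

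Among flocculation regulators, mbx2 rose 2.55-fold (log2 1.35, and 0.60 when the WT level was estimated without the WT arrays of project 582) and sre2 by 0.94, while lkh1 (-0.56, and -0.27 in that estimate), ssn6 (-0.46) and cbf11 (-0.38) fell. The log2 difference of pfl8 was 0.10 (adjusted p = 0.655) and of map4 -0.14, and without the WT arrays of project 582 they were 0.66 (adjusted p = 0.0129) and 0.53 (adjusted p = 0.0131). The pheromone regulator ste11 fell by 1.00 and rgs1 by 1.24, while mei2 rose by 0.86, and the calls of mei2, rgs1 and adg2 were lost when the WT level was estimated without the WT arrays of project 582. In WT of that project rec10 stood at 801 ± 21.3 (SD, n = 3), against 172 ± 3.24 (n = 3) and 290 ± 11.4 (n = 5) in WT of projects 488 and 529. The auxotrophic, flocculin, regulator, cell wall, G1/S, histone, mitosis, mating, P cell, M cell, meiosis, iron uptake, phosphate and zinc, mRNA decay and zinc finger lists did not pass in the planned fit.

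In all 815 genes changed, 266 higher and 549 lower, of which 31 rose and 22 fell at least 2-fold. Setting array medians equal moved the median of all genes by 0.11 on the log2 scale and the split to 434 higher and 272 lower, and quantile normalization moved it to 352 and 391. Without cbf12-null replicate 3 the count was 490.

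Loss of Cbf12 in cells without Zfs1 was compared through the double null and the zfs1-null strain. The flocculin pfl8 fell 3.90-fold (log2 -1.96 ± 0.16 SE, adjusted p = 2.6e-07), from 766 ± 46.8 (SD, n = 3) to 201 ± 51.2. The sexual differentiation gene mei2 fell 5.35-fold (-2.42 ± 0.16, adjusted p = 5.3e-08), the hexose transporter ght1 4.92-fold, grt1 4.18-fold, the glycerol dehydrogenase gld1 3.60-fold, the transcription factor rsv1 3.44-fold and the invertase inv1 3.37-fold. Higher were gst2 (1.99), abp2 (1.29), the kinetochore protein cnp3 (1.24), meu10 (1.11), mug153 (1.10), ura4 (1.02), eta2 (0.89) and mrpl39 (0.82). The genes cnp3 and abp2 are neighbours in the annotation. The uracil synthesis gene ura4 is a common selection marker, and its signal was 1595 ± 97.9 in the zfs1-null strain of project 582, 2513 ± 288 in WT and 3243 ± 137 in the double null.

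Of 10 subtelomeric genes 5 fell, among them aes1 (-1.13) (camera adjusted p = 2.3e-05, adjusted p = 0.0244 with an estimated correlation). Of 8 hexose transporters 4 fell and ght8 rose by 0.45 (0.00329, adjusted p = 0.0885 with an estimated correlation). Of 13 iron uptake genes 5 fell, with frp1 at -1.14 (0.00329, adjusted p = 0.102 with an estimated correlation), and of 26 mating genes 8 fell, with rgs1 at -1.59 (0.00718, adjusted p = 0.244 with an estimated correlation). Of 18 core stress genes 6 rose and 2 fell (0.00329, adjusted p = 0.107 with an estimated correlation). Of 12 flocculation regulators sre2 rose (0.71) and cbf12 and mbx2 (-0.72) fell (0.00457, adjusted p = 0.107 with an estimated correlation and adjusted p = 0.0729 with the deleted genes left out), and the call of sre2 was lost without zfs1-null replicate 2. Of 112 ribosomal protein genes 6 rose (1.8e-17, adjusted p = 0.441 with an estimated correlation). Under quantile normalization the mating and ribosomal lists were lost (adjusted p = 0.0750 for both).

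In all 261 genes changed, 94 higher and 167 lower. The count was 156, 120 and 150 without zfs1-null replicate 1, 2 or 3, and 446 without double null replicate 1. Setting array medians equal gave 136 higher and 108 lower, and quantile normalization 107 and 87.

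The interaction asked directly whether the effect of cbf12 deletion depended on Zfs1. The largest differences were negative. The difference in log2 effect was -3.33 ± 0.11 SE for eno102 (adjusted p = 1.1e-11), -3.30 ± 0.22 for ght3 (7.4e-08), -3.28 ± 0.23 for mei2 (1.0e-07), -2.58 for uga1, -2.40 for mel1 and -2.28 for rsv1. It was -2.07 for pfl8 and -2.07 for mbx2, which rose on cbf12 deletion in WT and fell in the zfs1-null background. The signal of ght3 was 210 in WT, 120 in the zfs1-null strain, 1502 in the cbf12-null strain and 89.4 in the double null (n = 3 each). Positive values were found for cnp3 (1.88), meu27 (1.82), abp2 (1.51), mrpl39 (1.24), mug133 (1.23), the kinetochore gene sim4 (1.15), mfm1 (1.14) and num1 (1.09). The call of mfm1 was lost when all probe sets of both species were tested. With the WT level estimated without the WT arrays of project 582, the differences were 0.36 for meu27 and 0.05 for num1, which lost their calls, -0.70 for mfm1 (adjusted p = 0.0684), 0.31 for sim4, 0.48 for mug133, 0.57 for mrpl39, 1.10 for abp2 and 1.41 for cnp3. For eno102, ght3, mei2 and mbx2 they were -2.59, -2.51, -2.69 and -1.32.

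For the interaction, 4 of 10 subtelomeric genes (camera adjusted p = 7.8e-08, adjusted p = 0.00605 with an estimated correlation), 4 of 8 hexose transporters (9.2e-07, adjusted p = 0.00647 with an estimated correlation) and 7 of 18 core stress genes (7.8e-08, adjusted p = 0.0104 with an estimated correlation) were negative, and none of these were positive. Of 14 glycolysis genes 2 were negative (0.000768, adjusted p = 0.196 with an estimated correlation), and of 16 iron-using genes 2 (0.0377, adjusted p = 0.471 with an estimated correlation). These last 2 lists were lost without the WT arrays of project 582 (adjusted p = 0.659 and 0.861). In that estimate 5 others passed, namely mating (14 of 26 negative, adjusted p = 1.6e-05), M cell genes (3 of 7 negative, 0.0236) and flocculins (1 of 3 negative, 0.0216) downward, and ribosomal proteins (41 of 112 positive, adjusted p = 3.8e-10) and auxotrophic markers (5 of 15 positive, 0.0177) upward. In all 283 genes passed, 127 positive and 156 negative, and setting array medians equal gave 34.7 percent positive, against 44.9 percent. With the WT level estimated without the WT arrays of project 582 the count was 764, of which 234 were among the 283. In that estimate the zfs1 effect with Cbf12 present comes from the other projects. The 764 genes and the 5 other lists can therefore also reflect a zfs1 effect that differs between projects. They are not shown to depend on Cbf12. Across genes, the cbf12 effects with and without Zfs1 had a Pearson r of 0.27 and a Spearman value of 0.35.

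**Figure D2:**
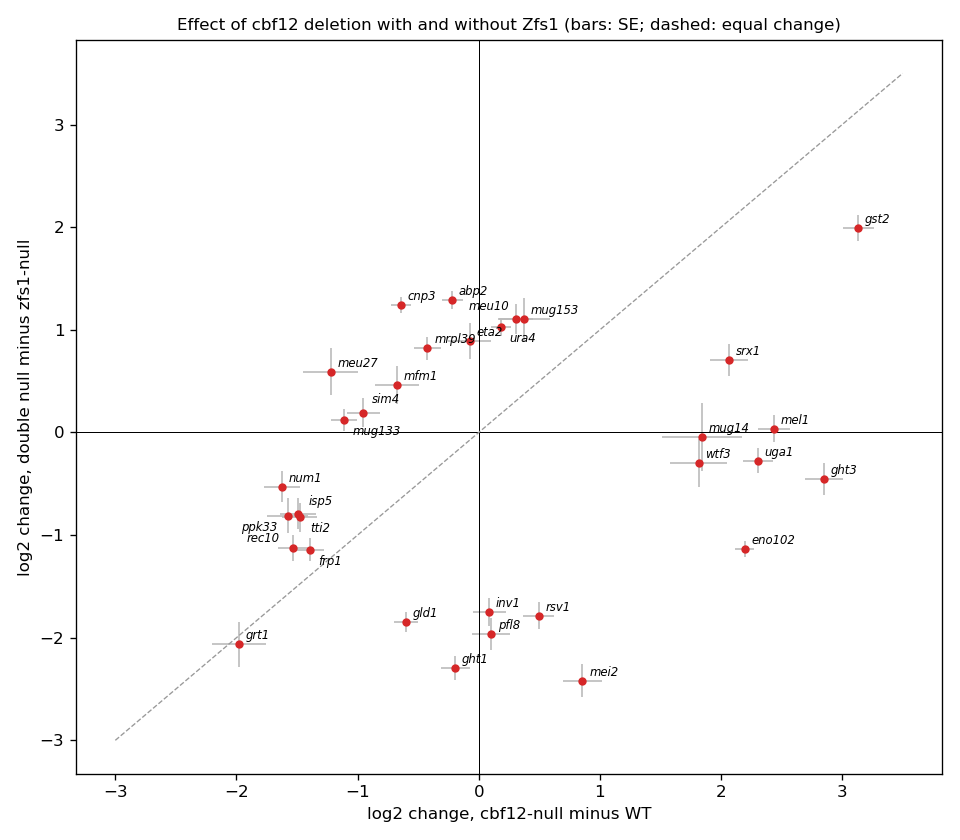
Log2 change on cbf12 deletion with Zfs1 present (x axis, cbf12-null minus WT) and with Zfs1 absent (y axis, double null minus zfs1-null) for the genes named for the cbf12 comparisons and the interaction, except cbf12. Points are estimates from 3 samples per strain, bars are SE and the dashed line marks equal change. The points of gst2 (3.13 and 1.99) and grt1 (-1.98 and -2.06) have the same sign on both axes, whereas ght3 (2.85 and -0.45) lies far below the line.

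Loss of Zfs1 in cells without Cbf12 raised arz1 3.37-fold (log2 1.75 ± 0.09 SE, adjusted p = 1.0e-09), against 1.83 with Cbf12 present. It also raised nth1 by 0.95 and mus7 by 0.92, while mei2 fell 26.7-fold (-4.74 ± 0.16, adjusted p = 3.8e-12) and ght3 17.1-fold. The flocculin pfl8, which rose without Zfs1 when Cbf12 was present, fell by 0.69 when it was absent (adjusted p = 0.00358). In all 980 genes changed, 546 higher and 434 lower. Setting array medians equal gave 424 higher and 435 lower, and quantile normalization 521 and 399. Against WT, the double null had arz1 higher by 1.78, gst2 by 1.60 and psl1 by 1.18 (0.68 without the WT arrays of project 582), and mei2 lower by 14.8-fold. That comparison called 1018 genes, 448 higher and 570 lower, and setting array medians equal gave 659 and 383.

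Genes that rose in projects 488 and 529 were then followed in project 582, whose arrays had no part in choosing them. Of 3 genes at least 2-fold higher, arz1, pfl8 and cbf12, 2 were called higher in project 582 in the fit of all 4 strains and 3 when adjusted over the list alone. Of 35 genes at least 1.5-fold higher, 23 were called higher and none lower in project 582, with a median log2 change of 0.56. On zfs1 deletion in the cbf12-null background, with cbf12 itself left out, 24 of the other 34 were called higher and 2 lower, with a median of 0.56.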

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

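The splits of the samples were planned before they were run, and all tests of explanations given here were chosen only after the result was seen.

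The effect of zfs1 deletion differed between projects for 571 genes. The largest difference between projects was 1.88 for mel1, 1.34 for eno102, -1.42 for meu10 and -1.79 for alr2, on the log2 scale. Among 100 splits of the arrays within projects, the real one alone gave as many genes, and the highest of the others gave 385. These splits also break up the zfs1 effect that the projects share. They therefore cannot show how many genes would pass if that effect were equal in all projects. For the combined comparison the real split gave 1207 genes and the highest of the other splits 422, and for project 529 the values were 1223 and 0. Of the 100 splits drawn for each of these 2 comparisons, only 1, the real one, reached the real count, so chance is argued against for these 2 counts.

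The effect of cbf12 deletion differed with Zfs1 for 283 genes, and among 100 splits the highest other than the real one gave 183. These splits shuffle all strain labels and so also break up the separate effects of the deletions. For that reason they cannot show how many genes would pass if the effects did not depend on each other. Positive differences were 1.88 for cnp3, 1.82 for meu27, 1.51 for abp2, 1.24 for mrpl39, 1.23 for mug133, 1.15 for sim4, 1.14 for mfm1 and 1.09 for num1. With the WT level estimated without the WT arrays of project 582, those of meu27, mfm1 and num1 were 0.36, -0.70 and 0.05. In that estimate those of sim4, mug133 and mrpl39 were 0.31, 0.48 and 0.57, and those of abp2 and cnp3 were 1.10 and 1.41. A zfs1 effect that differs between projects moves these values too, so the WT arrays are not shown to be the cause. Negative differences in the planned fit were -3.33 for eno102, -3.30 for ght3, -3.28 for mei2, -2.58 for uga1, -2.40 for mel1, -2.28 for rsv1, -2.11 for wtf3 and -2.10 for ght1. For groups of 3 against 3 there are 10 splits, too few for a share under 0.05. There the real value and the highest other were 570 and 0 for project 488, 327 and 0 for project 582, 815 and 0 for cbf12 deletion in WT, 1018 and 1 for the double null, 261 and 0 for cbf12 deletion without Zfs1, and 980 and 0 for zfs1 deletion without Cbf12.

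The first pattern weighed is the 31 genes at least 2-fold higher in the cbf12-null strain, such as gst2, ght3 and eno102, with a median log2 change of 1.37. Low WT arrays in project 582 are argued against as the whole cause only if the zfs1 effect is equal in all projects. With the WT level estimated without those arrays, the median was 1.22 (1.14 to 1.26 with each array left out) and 31 of the 31 were also called. The zfs1 effect of mel1 and eno102, both in this list, differed between projects. The estimate also uses the cbf12-null arrays on which the genes were chosen. A rise on cbf12 loss whatever the state of Zfs1 is argued against as well for the list as a whole, because between the double null and the zfs1-null strain the median was -0.055, with 12 of the 31 above 0. That holds for the list and not for each gene, since gst2 rose by 1.99 and srx1 by 0.71 in that comparison. A candidate explanation that stays open is a state of the cultures, since these genes as a list also differed between WT of projects 488 and 529, with a median absolute difference of 0.41 against 0.23 in lists matched on expression and 0.20 over all genes. A biological effect of Cbf12 that needs Zfs1 stays open as well and was not tested apart from it.

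The second pattern is the 21 genes at least 2-fold lower in the cbf12-null strain, cbf12 left out, with a median of -1.22. High WT arrays are argued against as the whole cause, because the double null against the zfs1-null strain, which uses no WT array, gave a median of -0.53 (-0.70 to -0.53 with each array left out). In that comparison 90.5 percent of them, 19 of 21, were lower. The hypothesis that Cbf12 raises these genes with and without Zfs1 predicts that direction, and only the direction was weighed. The median fall was smaller there than in WT. The direction held for the list and not for each gene, since meu27 (0.59) and mug133 (0.12) were higher there. In the planned fit the interaction passed for meu27 (1.82), mug133 (1.23) and num1 (1.09), among others. The size of the fall is less certain, since without the WT arrays of project 582 the median was -0.67 and 17 were called. Differences in the state of the cultures were not tested for these genes and remain open.

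The third pattern is that 67.4 percent of the genes called on cbf12 deletion in WT were lower. Scaling of the arrays may contribute, and 3 values were looked at. The 27 hybridization control probe sets had a median change of 0.30 (0.22 to 0.39 with each array left out), against -0.07 for S. pombe genes. After centring on the median 38.5 percent of called genes were lower, an outcome that centring itself largely fixes, and the other-species probe sets gave 0.06 near the floor of the arrays. Because the amount of control on each array is not known independently, scaling and a lower transcript level cannot be told apart, and no biological explanation was tested.

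Single arrays stood apart within groups of 5 in 6 of 203 tested pairs of gene and group. Chance gives about 1 in 20, or 10.15 pairs, so the 6 are fewer than chance alone would give. The array's signal and the mean of the other 4 were 5653 and 4408 for fba1 (WT of project 529, replicate 4), 1478 and 1427 for ght4 (zfs1-null, replicate 4), 183 and 145 for map4 (WT, replicate 1), 840 and 705 for mus81 (zfs1-null, replicate 3), 2368 and 2610 for rep2 (zfs1-null, replicate 5) and 480.2 and 653 for tms1 (zfs1-null, replicate 5).

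Probe sets without a listed gene also answered the loss of Zfs1. Of 5177 such probe sets 2255 lay above background. In the combined comparison 1778738_at rose by 2.76 and 1779048_at by 1.84 on the log2 scale, and 1775955_at (-1.95) and 1772678_at (-2.33) fell. The zfs1-null signal of 1775955_at was near background in projects 488 (6.14, against 22.8 in WT) and 529 (7.25, against 17.1). In project 582 it was 17.1, against 133 in WT. The files do not pair these probe sets with genes.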

How the results depend on the processing

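The planned filter on dim genes removed 0 genes and says nothing about stability, including for lists and correlations. Among 277 called gene values, 8022 alternatives were run, the 2-fold minimum not counted. The call held with its direction in 7560, was lost in 457 and turned direction in 5. Of the 277 values, 95 lost the call under at least 1 of these alternatives, and 48 when a single replicate was left out. The 2-fold minimum alone removed 177 of the 277 calls. Leaving out single replicates made 4284 of them, of which 249 lost the call. The cause was not tested unless given here. Sign changes of gene values numbered 93, of which 88 were in values that had not passed the test, and values are given here for called genes and for genes named in the text. The gene-by-gene weights, the minimum mean signal, the WT level without the WT arrays of project 582, and for lists the replicate block and leaving out deleted genes, were added after seeing the data. The search for AU-rich elements was not run.

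Counts are given in this order where all are named: combined, project 488, project 529, project 582, difference between projects, cbf12 deletion in WT, double null, cbf12 deletion without Zfs1, zfs1 deletion without Cbf12, interaction. A 2-fold minimum left 20, 25, 24, 30, 20, 53, 61, 28, 92 and 64 genes, as it removes small changes by construction. Replicate number as a block gave 1092, 617, 1259, 330, 532, 821, 1004, 235, 948 and 297, and whether the numbers pair the samples is left open. Of 22 arrays 12 resembled their own number most, where random numbering gave a mean of 6.01 and at least 12 in 5.20 percent of 10000 draws. Testing all probe sets of both species, a larger number of tests, gave 1881 (combined), 869 (488), 1874 (529), 508 (582), 466 (cbf12 without Zfs1), 1528 (zfs1 without Cbf12) and 504 (interaction). Without a project term the combined count was 481. Under quantile normalization the difference between projects was 323 and the double null 604. With only the 2 groups compared, so fewer arrays, the double null gave 599 and cbf12 without Zfs1 164.

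Default array weights gave 1173 (488), 1277 (582), 1193 (difference between projects), 1670 (cbf12 in WT), 1577 (double null), 587 (cbf12 without Zfs1) and 789 (interaction). Their estimation stopped before convergence in 7 of 10 fits, and gene-by-gene weights, chosen after those counts were seen, gave 1043, 1048, 1096 and 1490 for the first 4 and 577 for the interaction. Those weights depend on the order of the genes, here by name, and over 20 random orders the counts were 1008 to 1082 (488), 1012 to 1121 (582), 1061 to 1147 (difference between projects), 1464 to 1542 (cbf12 in WT) and 534 to 615 (interaction).

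Leaving out each replicate gave 312 to 759 for project 488 (lowest without WT replicate 2), 183 to 544 for project 582 (lowest without zfs1-null replicate 2, highest without double null replicate 2), 490 to 1068 for cbf12 in WT (lowest without cbf12-null replicate 3) and 120 to 446 for cbf12 without Zfs1 (lowest without zfs1-null replicate 2, highest without double null replicate 1). Where 2 arrays remained in a group, the pooled spread was used. The other counts stayed within 1.5 times.

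The list from projects 488 and 529 at 1.5-fold had 23 of 35 genes called higher in project 582 and 24 without Cbf12. The 2-fold list under quantile normalization held 7 genes, against 3, of which 5 and 4 were called higher. Pearson correlations under quantile normalization were 0.67 (488 and 529), 0.59 (488 and 582), 0.68 (529 and 582) and 0.42 (zfs1 with and without Cbf12). With a mean signal of at least 100 they were 0.61, 0.64, 0.61 and 0.48. With an estimated correlation 1, 1, 1 and 3 lists passed in the combined, cbf12 in WT, cbf12 without Zfs1 and interaction comparisons. With fry 14, 11 and 8 passed in the last 3, and under quantile normalization 4 passed for cbf12 in WT. The replicate block left the number of lists at 12, 7, 7 and 5. With the deleted genes left out it was 12, 7, 6 and 5, and with the WT level estimated without the WT arrays of project 582 it was 4 for cbf12 in WT and 8 for the interaction.

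Among the sign changes, 5 were in called values. ght7 in the combined comparison was 0.18 under quantile normalization, and with the WT level estimated without the WT arrays of project 582 the cbf12 effect in WT was 0.35 for mam1 (adjusted p 0.0717) and 1.16 for mfm1 (0.00354), which so passed the test the other way. In the planned fit mfm1 was at -0.67, and its second probe set (-0.41) did not pass (adjusted p = 0.510). The WT level without the WT arrays of project 582 also moves with a zfs1 effect that differs between projects. With it the interaction count was 764, and the interaction turned to -0.41 for meu10 (adjusted p 0.0308) and -0.70 for mfm1 (adjusted p 0.0684). The rest had not passed the test. With that WT level, the interaction was -0.33 for map4, -0.080 for yox1 and 0.42 for zfs1, and for cbf12 in WT map4 was 0.53 (adjusted p 0.0131), zfs1 -1.95 and adn3 -0.018. Under quantile normalization sre2 was 0.013 in the combined comparison. For cbf12 in WT, adn3 was -0.20 with default weights, -0.15 with gene-by-gene weights and -0.15 to 0.22 as single replicates were left out. For the interaction, default weights gave 0.0026 for adn3 and 0.0014 for tup11, and leaving out replicates gave -0.12 to 0.038 for tup11, -0.028 to 0.16 for ldb1 and -0.036 to 0.21 for yox1. The ribosomal proteins turned direction for cbf12 in WT under quantile normalization (adjusted p 0.212). The zfs1 values rest on strains without the gene, whose signal lies near or below background, so their size and sign carry no meaning. The cause of the other changes was not tested.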

Other observations

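The tests of explanations here were chosen only after the result was seen.

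An unlisted probe set, 1778738_at, was higher without Zfs1, and is described after its values were seen. Its signal was 64.4 ± 5.60 (SD, n = 3), 86.8 ± 7.18 (n = 5) and 158 ± 25.6 (n = 3) in WT of projects 488, 529 and 582, and 805, 545 and 654 in the zfs1-null groups. In the cbf12-null strain it was 13.3 and in the double null 56.7. On cbf12 deletion without Zfs1 it fell by 3.53 on the log2 scale, and the pfl8 transcript by 1.96. The other effects in project 582 differ from those of pfl8, which did not pass the test on cbf12 deletion in WT (0.10, and 0.66 with adjusted p = 0.0129 without the WT arrays of project 582) and fell on zfs1 deletion without Cbf12 (-0.69).

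Sets of genes that fell without Zfs1 moved in both directions without Cbf12. Of 16 genes at least 2-fold lower on zfs1 deletion in projects 488 and 529, zfs1 left out, 13 were called lower in project 582. On cbf12 deletion in WT 8 of them were higher and 3 lower, with dak2 at 1.07 and isp5 at -1.49. Without the WT arrays of project 582 the counts were 6 and 3, and dak2 was at 0.27 and isp5 at -1.75. On cbf12 deletion without Zfs1 2 of the 16 were higher and 6 lower, with a median of -0.16. On zfs1 deletion without Cbf12 15 of the 16 were lower.

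One hypothesis was that the rise of genes without Zfs1 runs through cbf12, whose own transcript rises. It predicts a smaller rise where cbf12 is deleted. For the 34 genes at least 1.5-fold higher in projects 488 and 529, with cbf12 left out as it is deleted in both strains compared, the median change on zfs1 deletion in the cbf12-null background was 0.56 (0.48 to 0.67 with each array left out), against 0.54 with cbf12 present, and 32 of the 34 lay above 0. The list as a whole therefore argues against that route, whereas pfl8, chosen here after its values were seen, went the other way in the cbf12-null background, by -0.69. The other gene below 0 there, rgs1 (-0.85), was already below 0 in project 582 with cbf12 present (-0.51), and its interaction did not pass (-0.35, adjusted p = 0.392). For pfl8 the values are consistent with a need for Cbf12, a hypothesis formed on these data and not tested elsewhere.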
